A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

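Total RNA of a mid2 mutant, with and without Congo Red, was reverse transcribed with Cy5 or Cy3 nucleotides and hybridised on 2 two-channel arrays with the dyes swapped, per the labels' protocols. The labels speak of 2 cultures with a swap each, that is 4 arrays, while 2 samples were analysed here, and they do not say whether these hold 1 culture or 2. The deposited values form 1 table with a single log2 ratio per feature and array. That the scale is log2 was read from the values: 2 to the power of each of the 2832 and 3440 values is a ratio with 4 decimals, within a relative tolerance of 3e-09, against 9 and 7 values for base 10 within the same tolerance. The medians of the deposited columns were −0.28 on array 1 and −0.23 on array 2, so they were not centred on the median. The channel order, the scanner, any normalization within arrays, and any filter of cells are not given in the sources used here. No intensities were at hand, so signal over background was unknown. Why a cell is empty is not given either, and list members without a value were left out of their list's test.

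Ratios were used as deposited, with no further centring. By a rule fixed before the data were examined, columns that correlate positively are taken as already turned to treated over untreated, a reading that the labels do not settle. The control features 3XSSC and Arabidopsis were left out of the 6207 features, and each feature name occurred once. Feature names are systematic open reading frame names. They were matched to locus tags of a gene table of assembly R64, used for names and gene lengths only, of which 5654 matched and 553 did not; no genome build is named for the array, and no coordinates are given.

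The 2738 features with a value on both arrays entered the comparison. The mean ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A rule of size stood beside it: a mean of at least 2-fold, with the same sign and at least 1.5-fold on each array. The same limits applied to features with opposite signs gave a background count. A dye effect cancels in the mean only if the ratios had been turned. In 20 simulations of 2 arrays with 200 changed genes among 2738, limma recovered 4.8% of 2-fold, 71.7% of 4-fold and 92.5% of 8-fold changes at 7.75 false calls per simulation. The rule of size recovered 44.2%, 96.7% and 99.1% at 50 false calls per simulation. The arrays here have heavier tails and unequal spread, so these rates describe the simulated case.

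Gene lists written before the data were examined were tested with camera at a preset correlation of 0.01 when at least 3 members were measured, with adjustment over the lists. Beside it stood camera with an estimated correlation, fry and 10000 random lists of the same size. Fry asks whether a list moves one way and does not compare it with other genes. Camera with an estimated correlation and fry rest on 1 residual degree of freedom here, so either could hardly call any list. On the deposited ratios themselves, 3.2% of 500 lists of 20 features drawn at random had p under 0.05 with camera. Each of 100 such lists with a shift of 0.5 added was recovered. Features drawn at random need not move together, so the 3.2% does not give the rate of false calls for lists of co-regulated genes. The genes named were fixed by rule: the 12 highest and 12 lowest means past the gene test, filled up from the rule of size where too few passed, the 2 highest and 2 lowest members of each list spoken of, and a fixed set of wall, marker and control genes. Features not matched to a gene were left out of naming, except YFL032W and the genes said to be chosen after their values were seen.

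Alternatives planned before the data were examined were centring, scaling and quantile normalization of the arrays, turned signs, other thresholds and fold limits, robust moderation, a filter on the difference between arrays, features with a value on either array, each array left out, and lists without shared members. A reading of the ratios as never turned, rank correlation, an adjusted p under 0.10 after scaling or quantile normalization, and subsets of features and members were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.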

Results

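Transcript ratios were measured in a mid2 mutant of the budding yeast Saccharomyces cerevisiae, made in BY4741, a haploid laboratory strain of mating type a. Mid2 is a plasma membrane sensor of the cell wall integrity pathway, the kinase cascade that ends in Slt2 and its transcription factor Rlm1. Congo Red is a dye that binds chitin and glucan and disturbs the assembly of the wall. The comparison asks how transcript levels respond to this wall stress when the sensor is missing. No wild-type array was analysed here, so no value below can be tied to the lack of Mid2. Cells grown in rich medium at 24 °C were exposed to 30 µg/ml Congo Red for 4 h, and their RNA was hybridised on the same array with RNA of the untreated part of the culture. The single group held 2 arrays with swapped dyes: treated RNA carried Cy3 on array 1 and Cy5 on array 2. Array 1 gave a value for 2832 of 6207 features and array 2 for 3440, and 2738 features had a value on both. The number of arrays limits the precision of every value below.

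The direction of the ratios is not settled by the labels or the table. The columns correlated positively across features as deposited (Pearson r = 0.48, Spearman rho = 0.34, genes not being independent replicates), although the dyes were swapped. Ratios that had been turned to treated over untreated on both arrays would do so, and a positive ratio is therefore read here as higher with Congo Red, a reading that is not settled. The correlation bears only on whether both columns share an orientation. That the orientation is treated over untreated rests on the repository's request for test over reference. Ratios turned to untreated over treated would correlate as well, and each direction read below would then be the opposite. All 2832 and 3440 ratios have 4 decimals within a relative tolerance of 3e-09, but only 3 and 4 of their inverses do. Neither column was thus inverted after rounding, and turning before rounding stays open. Ratios of fixed channel order with a strong dye bias per gene would also correlate positively. In that case the values below measure the dyes, and the treatment lies in the difference between the arrays. The control feature 3XSSC, by its name a buffer with no gene, had 0.48 on array 1 and 0.51 on array 2. A dye offset alone gives equal signs in ratios never turned and opposite signs in turned ones. The Arabidopsis control had opposite signs, −2.52 on array 1 and 0.53 on array 2. Single control features, looked at after the values had been seen, do not settle the direction. All list positions are given relative to the median of all features, which was −0.24 on the log2 scale. Values of single genes are given as deposited, so a gene near −0.24 lies at that median.

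The median members of the gene lists of glycolysis, cell wall integrity reporters, chaperones, ergosterol synthesis and amino acid synthesis lay above the median of all features on both arrays, the side read as higher with Congo Red. These lists passed camera at its preset correlation. With an estimated correlation none of them was called (adjusted p = 0.963 with camera for each). That form rests on 1 residual degree of freedom and could hardly call any list. PDC6, encoding a pyruvate decarboxylase, had a mean log2 ratio of 3.35 ± 1.34 (SD, n = 2), and PMA1, the proton pump of the plasma membrane, 3.03 ± 1.39 (SD, n = 2). PIR3, a wall protein and common reporter of the cell wall integrity pathway, stood at 2.27 ± 1.58 (SD, n = 2). On the negative side stood FAS2, a subunit of fatty acid synthase, at −2.37 ± 0.36 (SD, n = 2). No single gene passed the test: limma called 0 of 2738 features at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.123. At an unadjusted p under 0.05 limma gave 371 features, 172 positive and 199 negative. The nominal number, were every true mean 0, is 136.9. As the median of all features was −0.24 and not 0, part of the count can come from that offset, and centring gave 303. The same test on centred ratios read as never turned gave 15, so 136.9 is not a background measured on these arrays. The rule of size, a mean of at least 2-fold with at least 1.5-fold in the same direction on each array, took 113 positive and 77 negative features. Only 11 features met the same limits with opposite signs on the arrays, 7 positive on array 1 and 4 positive on array 2. Were the ratios never turned, these 11 would be the features past the limits. Centring each array moved the split of 113 and 77 to 162 positive and 35 negative, so that the positive share went from 59.5% to 82.2%. Taken alone, array 1 had 577 features of at least 2-fold and array 2 had 155.

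**Figure D1:**
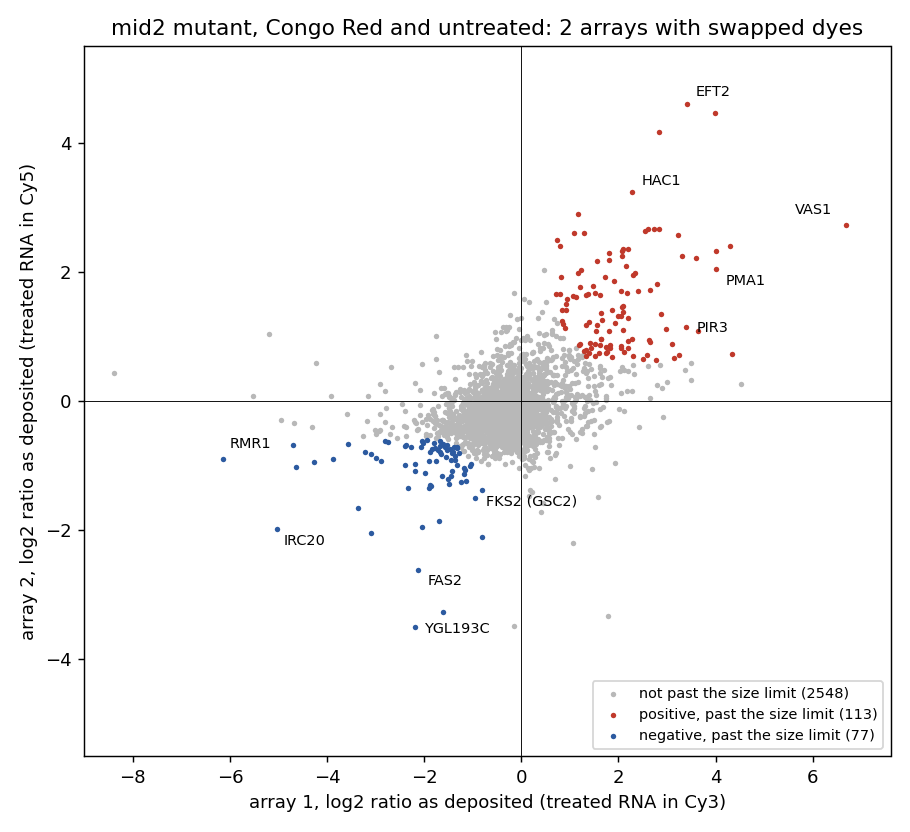
Each point is 1 of 2738 features, with its deposited log2 ratio on array 1 (treated RNA in Cy3, horizontal) and array 2 (treated RNA in Cy5, vertical); red and blue mark the 113 positive and 77 negative features past the limits of size. Most large ratios lie in the quadrants of equal sign, array 1 is wider (SD 0.96) than array 2 (SD 0.57), and several features at −4 or below on array 1 lie near 0 on array 2.

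Among the genes that the strain lacks in whole or part, MID2 itself had no value on either array, nor had MET17 and URA3. Both RNAs on each array came from the mutant, so a ratio of MID2 could not have checked the mutation either. HIS3 gave −0.27 ± 0.15 (SD, n = 2) and LEU2 −0.10 ± 0.22 (SD, n = 2), the latter with its sign turned to 0.13 by centring. Where neither RNA holds the transcript, a ratio shows noise or cross-hybridisation and nothing of the treatment. A value on both arrays is therefore no proof that a transcript was there. ACT1, the actin gene, gave 0.71 ± 0.35 (SD, n = 2). The list of alpha-cell genes, markers of cells of the other mating type, had 2 members with values and was not tested.

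Of 33 gene lists fixed before the data were examined, 31 had enough members to test and 8 passed camera at its preset correlation of 0.01, each shifted to the positive side. None of the 8 passed with a correlation estimated from the 2 arrays, where the smallest adjusted p was 0.963. In that form the estimate and the test itself rest on 1 residual degree of freedom, so hardly any list could pass. The estimates for reporters (−0.048), mannoproteins (−0.027) and mannosylation (−0.043) lay below the preset 0.01, and those of the other passing lists above it. A higher correlation was thus not why these named lists were lost. No list passed fry, whose smallest adjusted p was 0.340. Fry rests on the same 1 degree of freedom, so its lack of calls cannot decide whether a list shifted. The comparison with 10000 random lists was passed by 11. Both forms of camera and the random lists set a list against other genes, which fry does not. Only the random lists use the mean ratios alone. Limma, fry and both forms of camera, at the preset correlation too, rest on the spread between the 2 arrays. That spread may be technical, since the labels do not say whether the arrays hold separate cultures. With the ratios read as never turned, an alternative chosen after seeing the data, 4 lists passed camera: glycolysis, chaperones, ergosterol and, not among the 8, ribosomal proteins.

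In the mean of the arrays as deposited, glycolysis and fermentation showed the widest shift of the 31 lists, while on array 2 the cell wall integrity reporters lay higher (0.82 against 0.65). With the ratios read as never turned, as Cy5 over Cy3, the glycolysis shift was −0.29 (adjusted p = 0.00700 with camera) and that of ergosterol synthesis was widest at −0.45. The median of the 20 measured glycolysis and fermentation genes lay 0.89 above that of all features (adjusted p = 6.74e-11 with camera), at 1.23 on array 1 and 0.65 on array 2, and adjusted p = 0.963 with an estimated correlation. Of these members 19 lay above the median of all features on both arrays, 8 passed the limits of size, all positive, 0 passed limma over all genes, 9 had an unadjusted p under 0.05 and 7 passed when adjusted over the list alone. PDC6 and PGI1, the phosphoglucose isomerase gene, were highest, PGI1 at 2.91 ± 0.97 (SD, n = 2). TPI1, triosephosphate isomerase, gave 0.02 ± 0.27 (SD, n = 2), and PFK26, which makes a regulator of the pathway rather than a glycolytic enzyme, gave −0.83 ± 0.93 (SD, n = 2). PDC6 has close copies in PDC1 and PDC5, and cross-hybridisation among them cannot be separated here. Hexose transporters and their regulators, by contrast, had a median of −0.62 relative to all features over 7 members, at −0.67 on array 1 and −0.18 on array 2, and at 0.31 with the ratios read as never turned, as Cy5 over Cy3 (adjusted p = 0.156 with camera). As deposited they did not pass camera (adjusted p = 0.167, and adjusted p = 0.972 with an estimated correlation) but passed the random lists (adjusted p = 0.0124). HXT3, a low-affinity glucose transporter, gave −1.57 ± 1.75 (SD, n = 2) and MTH1, a regulator of transporter genes, −1.69 ± 1.00 (SD, n = 2), whereas HXT1 gave 0.53 ± 0.56 (SD, n = 2) and HXT4 gave −0.24 ± 0.52 (SD, n = 2), the last turned to 0.054 by scaling the arrays.

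The cell wall integrity reporter genes, which textbook accounts name as induced through Slt2 and Rlm1, lay 0.77 above all features in the median of 22 measured members (adjusted p = 4.58e-05 with camera), at 0.58 on array 1 and 0.82 on array 2, and adjusted p = 0.963 with an estimated correlation. With the ratios read as never turned, as Cy5 over Cy3, the shift was −0.055 and did not pass camera (adjusted p = 0.612). On both arrays 14 of the 22 lay above the median of all features. The limits of size took 4 positive members and 1 negative one. Limma called 0 of them over all genes, 8 at an unadjusted p under 0.05 and 3 when adjusted over the list alone. Beside PIR3 the positive ones were NCW2, a wall protein (1.46 ± 0.29, SD, n = 2), SED1, an abundant wall glycoprotein (1.36 ± 0.26, SD, n = 2), and CRH1, which links chitin to glucan (1.25 ± 0.11, SD, n = 2). PST1 gave 0.61 ± 0.38 (SD, n = 2) and CWP1 0.51 ± 0.61 (SD, n = 2). FKS2, the stress-induced glucan synthase listed as GSC2 in the gene table, pointed the other way at −1.22 ± 0.39 (SD, n = 2). RLM1 gave −0.73 ± 0.18 (SD, n = 2) and the chitin synthase gene CHS3 −0.31 ± 0.06 (SD, n = 2). Relative to the median of all features these were −0.49 and −0.068. SLT2 had a value on array 2 only, 0.35, and its paralogue KDX1 on array 1 only, −1.51, while GFA1 and HSP12 had none. The 7 measured components of the pathway itself did not pass camera (median −0.066 relative to all features, −0.13 on array 1 and −0.11 on array 2, adjusted p = 0.410); ROM1 and RHO1 gave −0.19 ± 0.30 and −0.20 ± 0.29 (SD, n = 2), turned by centring to 0.034 and 0.024, and BEM4 gave −0.58 ± 0.66 (SD, n = 2).

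Cell wall mannoproteins lay 0.28 above all features (25 members, adjusted p = 0.00849 with camera, and adjusted p = 0.963 with an estimated correlation), with 2 members past the limits of size on the positive side and 1 on the negative side, PRY3 at −1.96 ± 1.61 (SD, n = 2). FIT1, an iron-related wall protein, had ratios of −2.05 and 0.57 on the 2 arrays. Without the members that also stand in other lists this shift was 0.071 and no longer passed camera (adjusted p = 0.920). Mannosylation and GPI anchoring genes lay 0.30 above all features (23 members, adjusted p = 0.0114 with camera, and adjusted p = 0.963 with an estimated correlation). The protein O-mannosyltransferase genes PMT6 and PMT2 were highest at 1.34 ± 0.40 and 0.86 ± 0.21 (SD, n = 2), and the mannosyltransferase genes MNN2 and KTR5 lowest at −0.44 ± 0.09 and −0.52 ± 0.14 (SD, n = 2). Limma called 0 members of either list, over all genes or adjusted over the list alone, and 5 and 2 at an unadjusted p under 0.05. Chitin genes (12 members, shift 0.41, adjusted p = 0.106) and glucan genes (15 members, shift 0.36, adjusted p = 0.0677) did not pass camera. The chitin shift was 0.24 on array 1 and 0.16 on array 2, and the glucan shift 0.22 and 0.46. Their highest members were CRH1 and the chitinase gene CTS1 (1.19 ± 0.44, SD, n = 2), and SUN4, a wall protein of the septum (1.63 ± 0.23, SD, n = 2), with EXG1, the main exoglucanase gene (1.43 ± 1.24, SD, n = 2). The lowest were CHS1 (−0.69 ± 0.30, SD, n = 2) and CDA1 (−0.91 ± 0.61, SD, n = 2) among the chitin genes, and FKS2 and KRE1 (−1.32 ± 2.09, SD, n = 2) among the glucan genes. KRE1 had −2.80 on array 1 and 0.16 on array 2.

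**Figure D2:**
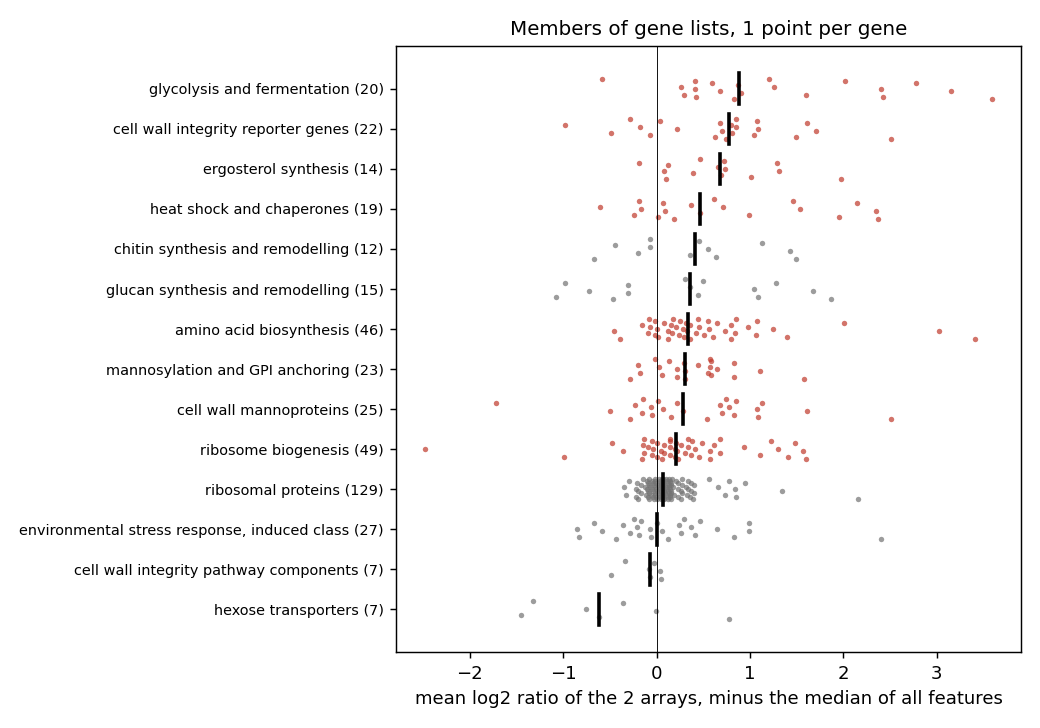
Each point is a gene of a list fixed before the data were examined, at its mean log2 ratio of the 2 arrays minus the median of all features (horizontal); black bars are list medians, numbers in brackets count the measured members, and red marks the 8 lists past camera at its preset correlation. Glycolysis (bar at 0.89) and the cell wall integrity reporters (0.77) lie farthest right, the 129 ribosomal protein genes near 0 (0.065), and hexose transporters to the left (−0.62).

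Heat shock proteins and chaperones lay 0.46 above all features in 19 members (adjusted p = 0.00258 with camera, and adjusted p = 0.963 with an estimated correlation), with a wider shift on array 1 (0.76) than on array 2 (0.25). HSP60, the mitochondrial chaperonin, gave 2.13 ± 0.04 (SD, n = 2) and SSE1, an exchange factor of Hsp70, 2.11 ± 1.08 (SD, n = 2), while HSP26 and HSP30 gave −0.48 ± 0.24 and −0.84 ± 0.57 (SD, n = 2). Limma called 0 members over all genes, 7 at an unadjusted p under 0.05 and 1 when adjusted over the list alone. The general stress genes of the Msn2 and Msn4 type did not pass camera, with the median of 27 members 0.0033 above all features (adjusted p = 0.910). Single members reached far, PRB1, a vacuolar protease, to 2.16 ± 0.12 (SD, n = 2) and SSA4 to 0.75 ± 0.39 (SD, n = 2), against HBT1 at −1.08 ± 0.85 and CYC7 at −1.09 ± 0.41 (SD, n = 2). The unfolded protein response genes had a median at that of all features (−0.0062 relative to it, 18 members) but a mean 0.39 above the mean of all features (adjusted p = 0.337 with camera). The highest members were HAC1, the transcription factor of this response, with 2.76 ± 0.67 and SEC61, a channel of the endoplasmic reticulum, with 2.04 ± 0.35 (SD, n = 2). OPI3 and MPD2 gave −0.42 ± 0.12 and −0.73 ± 0.24 (SD, n = 2). HAC1 shares sequence with the overlapping frame YFL032W, whose feature gave 1.99 ± 0.27 (SD, n = 2), and these values are not independent.

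Ergosterol synthesis genes lay 0.68 above all features (14 members, adjusted p = 0.000664 with camera, and adjusted p = 0.963 with an estimated correlation), again more on array 1 (0.92) than on array 2 (0.26). ERG11 and ERG1, encoding the targets of azoles and of terbinafine, gave 1.74 ± 0.64 and 1.07 ± 0.46 (SD, n = 2), and the regulator gene UPC2 and ERG28 were lowest at −0.16 ± 0.43 and −0.43 ± 0.35 (SD, n = 2), UPC2 being turned to 0.061 by centring. Amino acid biosynthesis genes lay 0.34 above all features (46 members, adjusted p = 8.26e-05 with camera, and adjusted p = 0.963 with an estimated correlation), at 0.36 on array 1 and 0.17 on array 2. ILV5, of branched-chain amino acid synthesis, gave 3.17 ± 1.19 and ASN2, an asparagine synthetase, 2.78 ± 0.75 (SD, n = 2), against SER3 at −0.63 ± 0.26 and ARG2 at −0.70 ± 0.48 (SD, n = 2). Of the ergosterol genes limma called 0 over all genes and 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05. Of the amino acid genes it called 0 over all genes and 3 when adjusted over the list alone, with 6 at an unadjusted p under 0.05.

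Ribosome biogenesis genes lay 0.21 above all features (49 members, adjusted p = 0.0271 with camera, and adjusted p = 0.972 with an estimated correlation), at 0.37 on array 1 and 0.063 on array 2. Limma called 0 of them over all genes or adjusted over the list alone, and 5 at an unadjusted p under 0.05. The helicase gene DBP2 and the pseudouridine synthase gene CBF5 were highest at 1.35 ± 1.84 and 1.33 ± 1.23 (SD, n = 2), RRP9 gave −1.23 ± 0.81 (SD, n = 2), and DBP8 had −5.52 on array 1 and 0.079 on array 2. Ribosomal protein genes did not pass (129 members, shift 0.065, adjusted p = 0.878 with camera), and their median relative to all features was 0.21 on array 1 and −0.12 on array 2. RPS0A and RPL3 gave 1.91 ± 2.25 and 1.11 ± 1.03 (SD, n = 2), RPL39 and RPS10A −0.57 ± 1.44 and −0.59 ± 1.10 (SD, n = 2). The 23 lists that did not pass camera had adjusted p from 0.0563 to 0.978 and median shifts from −0.62 to 0.41. In 7 of them, the lists of histones, G2/M genes, respiration, iron, the unfolded protein response, multidrug resistance and calcium, the median, the mean and the direction of camera differed in sign.

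Because no gene passed limma, the 12 highest and 12 lowest means were taken from the genes past the limits of size. Their order holds only for ratios read as turned. With the ratios read as never turned, as Cy5 over Cy3, limma called KEL1 (4.41), MSS51 (3.12) and DBP8 (2.80), log2 ratios of treated over untreated. These calls were lost with centring. VAS1, a valyl-tRNA synthetase, was highest with 6.68 on array 1 and 2.73 on array 2 (adjusted p = 0.233 with limma). YGL088W followed with 4.22 ± 0.34 (SD, n = 2), then EFT2 and EFT1, near-identical genes of translation elongation factor 2, with 4.01 ± 0.85 and 3.49 ± 0.94 (SD, n = 2). The remaining positive genes were PDC6, ILV5, PMA1, PGI1, ASN2 and HAC1, given above, with YJR028W (2.90 ± 0.47, SD, n = 2) and YMR046C (2.75 ± 0.12, SD, n = 2), both Gag frames of Ty retrotransposons with near-identical copies. RMR1 was lowest with −6.15 on array 1 and −0.89 on array 2, followed by IRC20 with −5.04 and −1.98. YGL193C gave −2.85 ± 0.92, FRE6, a ferric reductase of the vacuole, −2.57 ± 0.74, and GYP5, a GTPase-activating protein of secretion, −1.99 ± 0.07 (SD, n = 2 each). The ceramidase gene YDC1 (−2.82 ± 2.56), the cytochrome oxidase subunit gene COX7 (−2.60 ± 2.36), YOR296W (−2.51 ± 1.20), CNM1 (−2.38 ± 2.11), COX23 (−2.12 ± 2.05) and GEP5 (−2.00 ± 1.72, SD, n = 2 each) were negative on both arrays and far lower on array 1. Of 12 features at −4 or below on array 1, 2 were at −1 or below on array 2.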

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

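Control features stood outside the comparison; they were looked at only after the values had been seen, and no explanation of them was tested. The feature named 3XSSC, by its name a spotting buffer with no gene, had a log2 ratio of 0.48 on array 1 and 0.51 on array 2, the same sign and size although the dyes were swapped. The Arabidopsis feature, by its name a plant sequence, had −2.52 on array 1 and 0.53 on array 2. The median of all features lay at −0.27 and −0.18 on the 2 arrays among features measured on both.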

How the results depend on the processing

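No paired analysis was possible because the study has 1 group and each ratio already pairs treated and untreated RNA. Settings on the ratios as never turned, rank correlation, matched features, the glycolysis subset and an adjusted p under 0.10 after scaling or quantile normalization were added after seeing the data. The limma count stayed at 0 with centring (303 at unadjusted p under 0.05), scaling (373), quantile normalization (483), turned signs (371), robust moderation (366), an adjusted p under 0.10 (371) and an added 1.5-fold limit, with smallest adjusted p from 0.0616 to 0.124. At an adjusted p under 0.10 it was 41 after scaling and 44 after quantile normalization. It was 384 when features whose arrays differ by more than 1 were left out, a filter that selects on the spread the test uses, and 3 with ratios read as never turned (KEL1, DBP8 and MSS51, at −8.38, −5.52 and −5.20 on array 1, chosen for naming after their values were seen), which became 0 with centring (15 at unadjusted p under 0.05). The count by size, 190, was 197 to 222 with centring, scaling or quantile normalization and 177 in matched features. It was 664 at 1.5-fold, 106 at 3-fold, 295 with no condition on single arrays, 412 in features with a value on either array, 155 to 577 with an array left out (577 on array 1 alone, the wider one), 11 as never turned and 16 with centring as well. The correlation of 0.48 was 0.34 by rank; the cause was not tested.

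The 8 list calls held with centring, scaling, quantile normalization (10 calls) and random lists (11). With an estimated correlation and with fry the count was 0, and these shifts were no longer called: reporters 0.77, mannoproteins 0.28, mannosylation 0.30, chaperones 0.46, ribosome biogenesis 0.21, glycolysis 0.89, amino acids 0.34 and ergosterol 0.68. Of fry's adjusted p the smallest was 0.340. Both tests rest on 1 residual degree of freedom and could hardly call any list, so these losses decide nothing about the shifts. Without shared members 7 were called, mannoproteins being lost at 0.071. Random lists added chitin (0.41), glucan (0.36) and hexose transporters (−0.62), and quantile normalization added glucan (0.41) and gluconeogenesis (0.37); the cause was not tested. Without PDC5, PDC6 and ENO1, which have close copies, the glycolysis shift was 0.83. Other genes of the list with close copies, such as the TDH genes, were kept, so this does not remove cross-hybridisation. As never turned, with Cy5 over Cy3, 4 lists passed camera with negative shifts, ribosomal proteins (−0.19), chaperones (−0.31), glycolysis (−0.29) and ergosterol (−0.45); with Cy3 over Cy5 the signs turn. No longer called were reporters (−0.055, adjusted p = 0.612), mannoproteins (0.027, 0.860), mannosylation (−0.0082, 0.860), ribosome biogenesis (−0.19, 0.0861) and amino acids (−0.12, 0.0861). Turning all signs multiplies each value by −1 and turns each direction without changing a count. Of 82 named genes with values on both arrays, 78 kept their sign with centring (not UPC2, ROM1, RHO1 and LEU2), 78 with scaling (not UPC2, ROM1, HXT4 and LEU2) and 82 with quantile normalization. The 24 highest and lowest kept theirs in all 3. With array 1 left out 75 of the 82 kept their sign, and with array 2 left out 78 did. Not run were features of a gene kept apart, as each name occurs once, and limma on 1 array, which has no residual degrees of freedom. Taken as 1 technical replicate the arrays allow no test, only the count by size. Signal over background was unknown, so which ratios rest on dim spots cannot be said.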

Other observations

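Ty retrotransposon frames, picked out after their values were seen, differed between shorter frames, taken as Gag, and longer frames, taken as Gag-Pol, by their length in the gene table. All 9 Gag frames that matched the gene table and had values on both arrays passed the limits of size, with a mean log2 ratio of 2.38 ± 0.44 (SD over 9 features), between 1.62 and 3.23 on array 1 and between 1.64 and 2.67 on array 2. Of 11 longer Gag-Pol frames 1 passed, YML045W at 1.83, and the mean of 0.012 ± 0.81 (SD over 11 features) averages 0.43 on array 1 (between −0.63 and 2.32) and −0.40 on array 2 (between −2.20 and 1.93). YAR009C came next with 2.32 on array 1 and 0.42 on array 2. In Ty1 and Ty2 elements both frames lie on the same transcript, and copies are near-identical, so these features are not independent. Which stretch of the element each feature carries is not given in the sources used here.

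In what follows, the tests of noise, abundance, dye bias and a Congo Red response, and the test without PIR3, were chosen only after the results had been seen. The first pattern is the set of 190 features of equal sign past the limits of size. Independent noise of single arrays would give as many features of opposite sign, but after centring 16 had opposite and 197 equal signs (exact binomial test, p = 7.95e-41, taking features as independent, which they are not). A ratio bias that follows transcript abundance alone would move the abundant ribosomal protein transcripts too, and their shift of 0.065 (95% interval from resampled genes, which leaves out the spread between arrays, 0.056 to 0.089) lay below 0.443, the glycolysis shift divided by 2, as it did on array 1 (0.21 against 0.62) and array 2 (−0.12 against 0.32). This comparison cannot exclude such a bias, because a treatment effect on ribosomal protein transcripts could offset it. The 2 lists were also not matched on gene length, which the mean ratio followed across features (Spearman rho = 0.20). A dye bias per gene in ratios never turned would give the correlation of 0.48, and a response to Congo Red in turned ratios would give it as well. The channel order is not stated and the control features do not settle it, so these explanations cannot be told apart.

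The second pattern is the positive shift of the cell wall integrity reporter genes. Against gene length as the whole cause, the list median stood at percentile 100 of 10000 random lists matched on length (one-sided permutation of genes, p = 1e-04, the smallest they can give). Set against 61 other cell wall genes with a mean of 0.060, the 22 reporters had a mean of 0.43, a difference of 0.37 (two-sided permutation test, p = 0.0339), or 0.52 on array 1 and 0.23 on array 2. That bound, written before the result, was met only with PIR3, since without it the difference was 0.29 (permutation p = 0.0930). As 1 gene decides the test, a shift of the reporters and a shift of all wall genes cannot be told apart, and a response to Congo Red and a dye bias both stay open.

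The third pattern is which features had a value at all. On chromosome arm YBR 87.0% of features were measured on both arrays, against 16.9% on YNR and 18.7% on YOL (simulated chi-square p = 1e-04 over 6207 features, the smallest 10000 draws can give). Across the 27 arms with at least 5 features that matched no gene, the measured share of such features followed that of matched genes (Spearman rho = 0.536, permutation p = 0.00484; Pearson r = 0.567, permutation p = 0.00206, and 0.567 without the 2 arms farthest from the median; 1 relation was computed). Features that match no gene can share sequence with a matched gene, as YFL032W does with HAC1. Their shares could then follow each other without a cause tied to position, so this relation cannot decide. Having a value also differed between gene lists. It held for 97.7% of ribosomal protein genes and 95.2% of glycolysis genes, against 44.1% of all features. Of the meiosis and sporulation genes it held for 7 of 39, and of the hexose transporters and their regulators for 7 of 22. A cause tied to the position of features on the array, in printing or hybridisation, is a candidate explanation. The differences between lists leave transcript abundance open as well, and no biological explanation was tested.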
